A study of Mus musculus with 6 samples.

How the data were processed

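RNA of Kupffer cells, the resident macrophages of the liver, was measured in 6 libraries, 3 from Trem2-deficient mice (Trem2_KO) and 3 from wild-type littermates (WT). Per the labels, the cells were sorted from male mice that were 8 weeks old at the start of 8 weeks of a high fat diet, and libraries were made from total RNA with an Illumina TruSeq kit. Groups and replicate numbers were taken from the sample titles. The labels do not say that each library is a separate mouse, so p-values measure the spread between these samples, which may be technical.

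The deposited read counts are whole numbers per gene with no normalization. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.16.1 with the builds GRCm38 and mm10. The strand setting, the treatment of reads that fit several genes and the design of any DESeq2 fit are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart, and genes with near-identical copies (the Mup, Serpina1 and H2 families, Hspa1a with Hspa1b) are uncertain. The deposited FPKM values equal the count divided by gene length and by 1 constant per library, and that constant was 0.989 to 1.02 times the library total. The origin of this constant is not given in the sources used here.

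Total counts ran from 15799351 to 17135603 per library. A count of 3 in a library, the limit that a count of 0 allows, corresponds to 0.175 to 0.19 CPM. This limit covers counting error only, since reads without molecular identifiers are not independent molecules.

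Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM scaling, estimateDisp, and the quasi-likelihood test with robust dispersion and genotype as the only term. Of 54532 genes, 13776 were tested, and these held at least 99.9% of the counts of each library. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes are those implied by the quasi-F statistic. CPM values are TMM-scaled and are given as mean ± SD with n = 3 per group.

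Before the data were examined, 34 gene lists, the tests, the rule for named genes and the alternatives were fixed. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over 33 lists, with an estimated correlation and fry beside it. Camera compares a list with all other genes, while fry tests whether its members move, on balance, one way. Called genes within 10 Mb of Trem2 were compared with all other tested genes by a two-sided Fisher exact test.

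Named genes are Trem2, the 10 largest rises and 10 largest falls among called protein-coding genes whose libraries do not overlap between groups and whose mean in the higher group is at least 5 CPM, up to 4 members of each list by smallest p (2 where no member was called), and the called neighbours of Trem2. Some genes that this rule selects are not reported here. Other genes named are marked as chosen after their values were seen.

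The test was run on simulated counts for the 13776 genes of this comparison, with 200 genes changed. In 10 draws edgeR recovered a mean of 51.8% of genes changed 1.25-fold, 74.4% at 1.5-fold, 84.4% at 2-fold and 98.4% at 4-fold. False calls made up a mean of 8.68% of edgeR's calls, between 5.39% and 13.1% over the draws, above the nominal 0.05, against a mean of 2.44% for DESeq2. The first draw gave 13.1%, and the other draws were added because of it. A simulation with 4000 genes changed 1.2-fold, also added then, gave a mean of 3.51% false calls and recovered 52% of the changed genes. With no gene changed, edgeR called between 0 and 8 genes and camera called 0 lists in 10 draws. With 1 list raised 1.2-fold, camera called it in 10 of 10 draws and called 1 other list over those draws.

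Alternatives were other scalings, filters and thresholds, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with a pseudocount of 1 or 0.1, removal of a gene length trend, the replicate number as a block, and leaving out each library. Fits with the biological coefficient of variation fixed at 0.1 and 0.2 were added after the data were seen.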

Results

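Kupffer cell RNA was compared between Trem2_KO and littermate WT mice after a high fat diet, with 3 libraries per group. TREM2 is a lipid-sensing receptor of macrophages, and the comparison asks which Kupffer cell transcripts depend on it in this diet. Total counts were 15799351, 15893041 and 15811116 in WT and 17135603, 16347967 and 16827173 in Trem2_KO. Pearson r of log2 CPM across genes, which are not independent replicates, was 0.9917 to 0.9931 between libraries of one group and 0.9819 to 0.9842 between groups. Counts within a group still differed by more than sampling noise (chi-square over degrees of freedom 1.98 to 2.93). Each library was counted as 1 sample, but this excess may be technical and does not show that each is a separate mouse. The first principal component held 53.6% of the variance and separated the groups.

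Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147, GRCm38) was read at 84.7, 90 and 84.2 CPM in WT and at 16.6, 17.3 and 14.5 CPM in Trem2_KO. Its log2 change was -2.42 (SE 0.064, n = 3 per group, edgeR adjusted p = 1.6e-35), in the direction of the labels in 6 of 6 libraries. Which part of the gene was deleted is not given in the sources used here, so the 246 to 288 reads left in each knockout library cannot be placed.

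**Figure D1:**
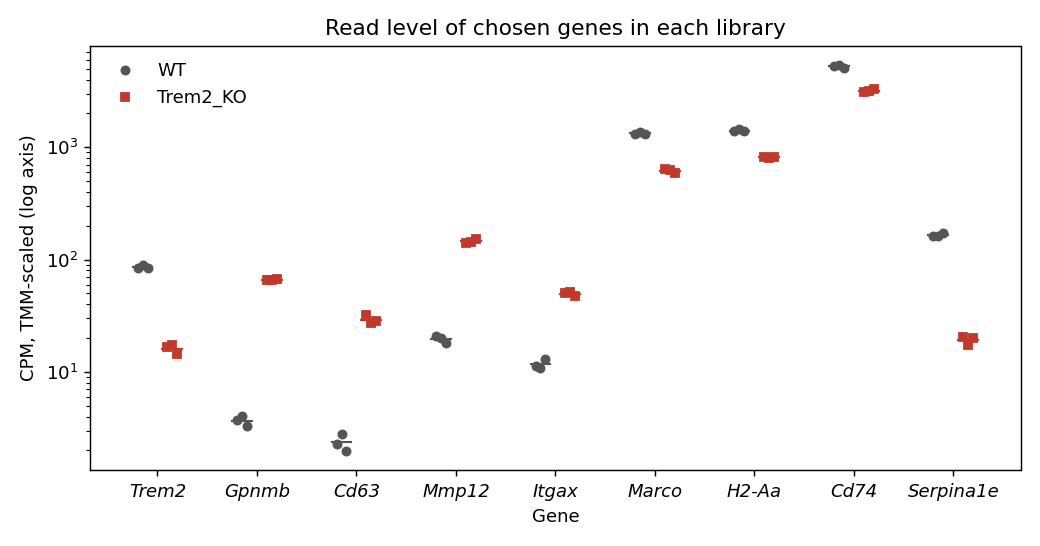
CPM of 9 genes (log axis) in each of the 3 WT libraries (circles) and 3 Trem2_KO libraries (squares), with horizontal lines at group means. For each gene the groups do not overlap, with Gpnmb at 3.68 CPM in WT and 66.1 CPM in Trem2_KO on average.

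Many genes changed, mostly by little. Of 13776 genes tested, 4181 were called, 2103 higher and 2078 lower in Trem2_KO, with a median absolute log2 change of 0.273. A fold of at least 2 was reached by 358 called genes, 273 higher and 85 lower. The 2 groups did not overlap for 41.6% of tested genes, against 10% by chance. With total counts in place of TMM the split was 2515 higher and 1592 lower, 61.2% higher against 50.3%. The estimated biological coefficient of variation was 0.0378, and with a value of 0.2 fixed for every gene, chosen after the data were seen, 371 genes were called.

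Genes known from lipid-associated macrophages were among those that rose most. Gpnmb, a lysosomal glycoprotein, went from 3.68 ± 0.352 to 66.1 ± 0.439 CPM (SD, n = 3), a log2 change of 4.16 (SE 0.0877, adjusted p = 3.74e-40). Spp1, which encodes osteopontin, rose by 3.77, the tetraspanin Cd63 by 3.63, the vacuolar ATPase subunit Atp6v0d2 by 2.90, and the elastase Mmp12 by 2.89 on the log2 scale. The integrin Itgax, not among the 10 largest rises, rose by 2.09. Of 27 tested members of the lipid-associated list, 14 were called higher and 9 lower, the same counts when adjusted over the list alone. The 9 falls were small, such as Lpl at -0.13 and Ctsb at -0.09, both chosen after their values were seen, so the median was 0.05 while the mean was 0.98. The list was called higher by camera (adjusted p = 4.9e-06, and adjusted p = 0.0447 with an estimated correlation). Sinusoidal endothelial markers rose in the same libraries, with a median log2 change of 0.44, and hepatocyte markers fell on balance (median -0.28). Of 16 monocyte markers, 5 were called higher and 2 lower.

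The other largest rises among called protein-coding genes with at least 5 CPM on average in Trem2_KO were Chst11, a chondroitin sulfotransferase (log2 change 4.42, SE 0.294), Cyp4a14 (3.61), Apoa4 (3.13), the collagenase Mmp13 (3.07) and the phosphatase Dusp5 (2.67). Chst11 had 3 to 5 reads per WT library and 97 to 107 per knockout library.

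Genes of the lipid uptake and storage list, which also holds lipase genes, rose. Of 21 tested members 12 were called higher and 0 lower, also when adjusted over the list alone. Pnpla2, the triglyceride lipase, rose by 0.41 (SE 0.0333) and Mgll, the monoglyceride lipase, by 1.01 (SE 0.146) on the log2 scale. The lipid droplet genes Plin4 and Cidec were read 0 to 2 times per WT library and 19 to 40 times per knockout library. Plin4 overlaps Hdgfl2 on the other strand. Plin4 and list member Plin5, called higher and chosen after its value was seen, lie 7.75 and 7.77 Mb from Trem2, where calls were denser. Of the 18 members further than 20 Mb from Trem2 or on other chromosomes, 10 were called higher and 0 lower. Sinusoidal endothelial markers rose (median 0.44) and hepatocyte markers fell on balance (median -0.28) in the same libraries. The list was called higher (adjusted p = 2.58e-05, and adjusted p = 0.0447 with an estimated correlation). Of 17 fatty acid synthesis genes, 9 were called higher and 0 lower, also over the list alone, led by the desaturase Fads2 (1.55), with Lpin2 at 0.28, Lpin1 at 0.47 and Thrsp at 0.50. That list's camera call (adjusted p = 0.0102) was lost at an adjusted p of 0.123 with an estimated correlation.

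Resident Kupffer cell genes fell. Of 24 tested members, 19 were called lower and 2 higher (20 and 2 when adjusted over the list alone), with camera adjusted p = 2.63e-10 and adjusted p = 0.0291 with an estimated correlation. The scavenger receptor Marco went from 1333 ± 21.4 to 618 ± 24.7 CPM (SD, n = 3), a log2 change of -1.11. The heme oxygenase Hmox1 fell by 0.46 and the iron exporter Slc40a1 by 0.38, while Vcam1 rose by 0.70. The median log2 change of the list was -0.15, and Clec4f, chosen after its value was seen, changed by -0.14. In the same libraries sinusoidal endothelial markers rose (median 0.44), and 5 of 16 monocyte markers were called higher and 2 lower.

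MHC class II presentation genes fell, with 10 of 12 tested members called lower and 0 higher, also over the list alone. Cd74, the invariant chain, went from 5249 ± 129 to 3198 ± 86.3 CPM (SD, n = 3), a log2 change of -0.71, and H2-Aa, H2-Ab1 and H2-Eb1 changed by -0.80, -0.81 and -0.77. Of the 12 tested members, 7 lie on chromosome 17 within 20 Mb of Trem2, H2-Aa at 14.1 Mb, and 6 of them were called lower, while 4 of the 5 others were called lower. B cells and dendritic cells also carry class II transcripts. In the same libraries 3 of 9 B and plasma cell markers were called lower and 0 higher. Of 10 dendritic cell markers 3 were called lower and 1 higher. The higher one, Clec9a, overlaps Clec1b of the resident Kupffer cell list on the same strand. Camera gave adjusted p = 1.88e-11, and adjusted p = 0.0291 with an estimated correlation. Of 31 interferon-stimulated genes, 15 were called lower and 0 higher (16 and 0 over the list alone), among them Ifi47 (-0.37), Zbp1 (-0.37) and Bst2 (-0.31). Camera gave adjusted p = 2.04e-06, and adjusted p = 0.0291 with an estimated correlation.

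**Figure D2:**
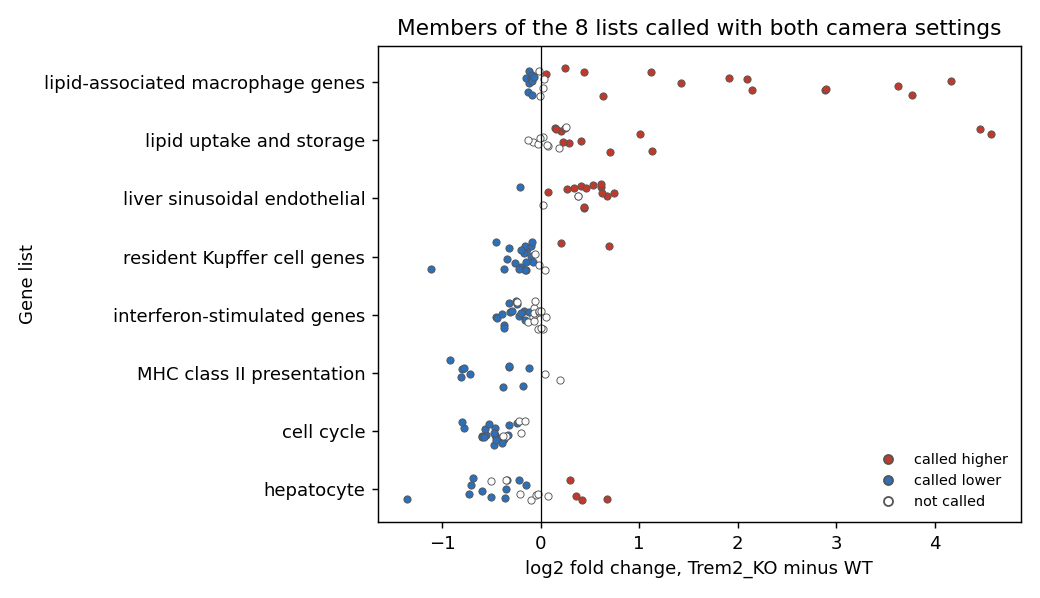
log2 fold change, Trem2_KO minus WT, of each tested member of the 8 lists called with both camera settings, 1 point per gene, spread vertically at random. Filled points were called. MHC class II genes reach -0.92, and lipid-associated macrophage genes hold both small falls and rises up to 4.16.

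Inflammatory cytokine genes went both ways, with 10 of 22 called higher and 5 lower (11 and 5 over the list alone). The chemokine Cxcl2 rose by 1.09 (SE 0.0398), the inhibitors Tnfaip3 and Il1rn by 1.02 and 1.11, and Nfkbiz by 0.61. The camera call (adjusted p = 0.00076) was lost at an adjusted p of 0.0579 with an estimated correlation.

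Cell cycle genes fell, with 20 of 25 called lower and 0 higher (21 and 0 over the list alone). Stmn1 fell by 0.78, Mcm2 by 0.60, Top2a by 0.59 and Mcm5 by 0.55 on the log2 scale. Camera gave adjusted p = 4.51e-10, and adjusted p = 0.0291 with an estimated correlation. Markers of other cells also moved in these libraries: endothelial ones rose (median 0.44) and hepatocyte ones fell on balance (median -0.28). Of 9 B and plasma cell markers 3 were called lower and 0 higher. Of 42 nuclear oxidative phosphorylation genes, 35 were called lower and 0 higher (39 and 0 over the list alone), among them Atp5o (-0.52), Cox5a (-0.34), Cox6a1 (-0.31) and Cox4i1 (-0.26). The camera call (adjusted p = 3.51e-14) was lost at an adjusted p of 0.139 with an estimated correlation. Of 35 cytosolic ribosomal protein genes, 17 were called lower and 1 higher (20 and 1 over the list alone), with Rplp1 at -0.25, Rplp2 at -0.20 and Rps6 at -0.14. That call (adjusted p = 2.97e-05) was lost at an adjusted p of 0.376 with an estimated correlation, and at 0.695 with the gene length trend removed (0.608 with the replicate block as well). Of 20 vesicle release genes, 5 were called lower and 0 higher, also over the list alone, with Flot1 at -0.34, Chmp2a at -0.24, Chmp4b at -0.20 and Sdcbp at -0.11. That call (adjusted p = 0.0365) was lost at an adjusted p of 0.382 with an estimated correlation, at 0.0942 without Trem2_KO replicate 2 and at 0.0712 without WT replicate 2. It was also lost with the gene length trend removed (0.127, and 0.132 with the replicate block), with total counts (0.071), with protein-coding genes only (0.057) and with a stricter filter (0.0516).

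Other pathway lists were not called by camera. Of 19 genes of Trem2 receptor signalling, 6 were called higher and 2 lower (7 and 2 over the list alone, camera adjusted p = 0.0648), with Ms4a4a at 1.61, Pik3r1 at 0.47, Sh2b3 at 0.21 and the adaptor Tyrobp at -0.22. The list passed with total counts (adjusted p = 0.0271), with unfiltered log2(FPKM + 1) (adjusted p = 0.0414) and with the gene length trend removed (adjusted p = 0.0482). LXR targets held 4 higher and 3 lower of 16 (6 and 3 over the list alone, adjusted p = 0.638), with Scd1 at 0.32, Abcg1 at 0.28, Abca1 at 0.21 and Smpdl3a at -0.17. Cholesterol synthesis held 3 higher and 2 lower of 24 (3 and 0 over the list alone, adjusted p = 0.579), with Insig1 at 0.23 and Pmvk at -0.36. Pmvk lost its call without each Trem2_KO replicate in turn and without WT replicate 2 or 3 (adjusted p = 0.0543 to 0.152). Fatty acid oxidation held 7 higher and 5 lower of 27 (7 and 7 over the list alone, adjusted p = 0.81), with Ppara at 1.93, Eci2 at 0.30 and Acaa2 at -0.25. Its median of -0.04 and mean of 0.11 differed in sign, as did camera (lower) and fry (higher). Glycolysis held 6 higher and 5 lower of 20 (7 and 5 over the list alone, adjusted p = 0.708), with Slc2a3 at 0.86, Pkm at 0.10, Eno1 at -0.13 and Hk3 at -0.23. Pkm lost its call without Trem2_KO replicate 1 or 2 or WT replicate 3 (adjusted p = 0.0691, 0.0517 and 0.0605).

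Of 33 lysosome genes, 3 were called higher and 9 lower, also over the list alone (camera adjusted p = 0.22), with Gla at 0.56, Hexa at -0.19 and Ctsh at -0.16. That list passed with no filter (adjusted p = 0.0266). Phagocytosis genes held 10 higher and 5 lower of 21, also over the list alone (adjusted p = 0.134), with Stab1 at 0.56, Cd300lf at 0.55, Mertk at 0.24 and C1qa at -0.21. Endothelial markers also rose (median 0.44), so the cell type behind rises such as that of Stab1 stays open. Alternative activation held 5 higher and 3 lower of 12, also over the list alone (adjusted p = 0.563), with Ccl17 at 1.69, Egr2 at 0.90, Ccl24 at -0.41 and Irf4 at -0.52. Profibrotic factors held 8 higher and 4 lower of 16, also over the list alone (adjusted p = 0.172), with Mmp13 at 3.07, Vegfa at 2.19 (2.33 Mb from Trem2), Mmp9 at 1.36 and Timp2 at -0.46. The stress response list held 3 higher and 8 lower of 18 (4 and 8 over the list alone, adjusted p = 0.119), with Atf3 at 0.79, Herpud1 at -0.44, Hspa5 at -0.32 and Hsp90b1 at -0.26. Immediate early and heat shock genes held 13 higher and 9 lower of 24, also over the list alone (adjusted p = 0.051), with Egr1 at 1.09, Fosb at 0.85, Hsp90aa1 at -0.75 and Hspa1b at -1.08. That list passed with the gene length trend removed (adjusted p = 0.0018, and 0.00221 with the replicate block as well), with no filter (0.0253) and with the replicate block (0.0464). It also passed without Trem2_KO replicate 1 (adjusted p = 0.0294) and without WT replicate 2 (adjusted p = 0.0387). Of 12 mitochondrially encoded genes, 2 were called higher and 0 lower, also over the list alone (adjusted p = 0.573), mt-Nd5 at 0.18 and mt-Cytb at 0.10, with mt-Nd6 at 0.08 and mt-Atp6 at -0.23 not called. Without WT replicate 3 mt-Atp6 was called (adjusted p = 0.0336). The list passed with the gene length trend removed (adjusted p = 0.000954, and 0.000622 with the replicate block as well).

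Markers of other liver cells moved in both directions. Sinusoidal endothelial markers rose, with 14 of 17 called higher and 1 lower (15 and 1 over the list alone), among them Flt4 (0.75), Ptprb (0.67), Ehd3 (0.61) and Eng (0.41). Camera gave adjusted p = 4.59e-07, and adjusted p = 0.0291 with an estimated correlation. Hepatocyte markers fell on balance, with 11 of 22 called lower and 4 higher (13 and 4 over the list alone, adjusted p = 2.58e-05, and adjusted p = 0.0447 with an estimated correlation). Mup3 fell by 1.35, Serpina3k by 0.72, Apoa1 by 0.71 and Ahsg by 0.68 on the log2 scale, while Alb, chosen after its value was seen, was at 805 ± 21.3 and 779 ± 23.3 CPM (SD, n = 3) and was not called. Of 16 monocyte markers, 5 were called higher and 2 lower, also over the list alone, with the chemokine receptors Cx3cr1 and Ccr2 at 1.46 and 1.45, Nr4a1 at 0.57 and Treml4 at -0.18. That call (adjusted p = 0.0365) was lost at an adjusted p of 0.166 with an estimated correlation and at 0.0619 without WT replicate 3. Cx3cr1 overlaps Csrnp1 and Gorasp1 on the same strand, which had 4149 and 2407 reads over the libraries. It also overlaps Wdr48 (4642 reads) on the other strand, so its reads may not all come from monocytes. Of 8 erythroid and platelet genes, 2 were called higher and 0 lower, also over the list alone, Hbb-bs (0.69) and Epor (0.28), with Hbb-bt at 0.95 and Hba-a1 at 0.31 not called. Without WT replicate 1 Hba-a1 was called (adjusted p = 0.00865). The camera call of the list (adjusted p = 0.0489) was lost at an adjusted p of 0.337 with an estimated correlation, at 0.0747 and 0.0722 without Trem2_KO replicate 1 or 3, and at 0.127 without WT replicate 3. It was also lost with a stricter filter (0.119), total counts (0.071), protein-coding genes only (0.0578), the replicate block (0.0544) and DESeq2 size factors (0.0504).

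The remaining cell type lists were not called. B and plasma cell markers held 0 higher and 3 lower of 9, also over the list alone (camera adjusted p = 0.139), with Ighm at -0.82, Cd79b at -0.32 and Cd22 at -0.20, and Ighd at 0.57 not called. Cd79b lost its call without Trem2_KO replicate 1 (adjusted p = 0.127) and without WT replicate 1 or 2 (adjusted p = 0.07 and 0.0747). Dendritic cell markers held 1 higher and 3 lower of 10 (2 and 4 over the list alone, adjusted p = 0.49), with Clec9a at 0.18, Batf3 at -0.18, Bst2 at -0.31 and Irf4 at -0.52, and camera pointed lower while median and mean were above 0. Batf3 lost its call without Trem2_KO replicate 3 (adjusted p = 0.0724), and Clec9a without Trem2_KO replicate 2 or 3 or WT replicate 1 or 2 (adjusted p = 0.0647 to 0.164). Clec9a overlaps Clec1b on the same strand, which had 36786 reads over the libraries, so its reads may not come from dendritic cells. Stellate markers held 3 higher and 0 lower of 12, also over the list alone (adjusted p = 0.673), with Col14a1 at 0.58, Hgf at 0.35 and Ecm1 at 0.32, and Colec11 at -0.59 not called, and camera pointed higher while median and mean were below 0. Colec11 was called without Trem2_KO replicate 3 or WT replicate 1 (adjusted p = 0.0267 and 0.0373). Neutrophil markers held 1 higher and 1 lower of 5, also over the list alone (adjusted p = 0.905), with Lcn2 at 1.76 and Csf3r at -0.10, and Mmp8 and S100a9 not called. Csf3r lost its call without Trem2_KO replicate 1 or 2 or WT replicate 3 (adjusted p = 0.0808, 0.16 and 0.165), and Lcn2 changed by 2.37 without WT replicate 1. T and NK cell markers held 1 higher and 0 lower of 4, also over the list alone (adjusted p = 0.62), Il7r at 1.94 (2.59 without WT replicate 2), with Cd4, Lck and Lat not called. For both of these lists the median was below 0 and the mean above 0. Of the cholangiocyte markers 2 could be measured, too few for a list test, Spp1 at 3.77 and Tstd1, not called, at -0.02. With DESeq2, Cd79b, Clec9a, Csf3r, Col14a1, Epor, Pmvk and Treml2 were not called. With the gene length trend removed, Batf3, Cd79b, Csf3r, Pmvk and Rps6 lost their calls (adjusted p = 0.138 to 0.377), and mt-Nd6 and Hba-a1 were called (adjusted p = 0.000106 and 0.0399).

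The largest falls were mostly transcripts known from hepatocytes. Serpina1e, an antitrypsin gene, went from 165 ± 6.11 to 19.3 ± 1.58 CPM (SD, n = 3), a log2 change of -3.10 (SE 0.0542, adjusted p = 1.07e-43). The transporter Slco1a1 changed by -3.17 and Selenbp2 by -3.72. The major urinary protein genes Mup15, Mup14, Mup7, Mup12, Mup11 and Mup17 changed by -5.69, -3.75, -3.48, -3.44, -3.03 and -2.56. Mup15 had 3, 10 and 3 reads in the Trem2_KO libraries, and its change was -6.51 without Trem2_KO replicate 2. The Mup and Serpina1 genes have near-identical copies and Selenbp2 has a close copy in Selenbp1, so single values are uncertain. 9130008F23Rik, on chromosome 17 at 7.47 Mb from Trem2, changed by -4.71 (SE 0.317).

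Called genes were more frequent near Trem2. Within 10 Mb, 65 of 143 tested genes were called (45.5%), against 4115 of 13632 elsewhere (30.2%), an odds ratio of 1.93 (95% interval 1.36 to 2.72, two-sided Fisher exact p = 0.000155). Genes are not independent, so this p is approximate. Within 20 Mb, which includes these genes, 158 of 363 were called, an odds ratio of 1.80 (1.45 to 2.23). In the 10 Mb window 19 of 143 tested genes were called with a fold of at least 2, against 338 of 13632 elsewhere. That is an odds ratio of 6.03 (3.47 to 9.95). The phospholipase gene Pla2g7 (1.70), the phosphatase gene Ptprs (1.54) and Pot1b (-1.23) are examples chosen after their values were seen. Of 7 tested genes of the Trem2 neighbour list, 2 were called higher and 2 lower (2 and 3 over the list alone, camera adjusted p = 0.308), Treml1 at 1.32, Treml2 at 0.40, Treml4 at -0.18 and Trem3 at -1.68. Treml2 lost its call without Trem2_KO replicate 1 or 2 (adjusted p = 0.195 and 0.0627) and without WT replicate 1 or 2 (adjusted p = 0.112 and 0.226).

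**Figure D3:**
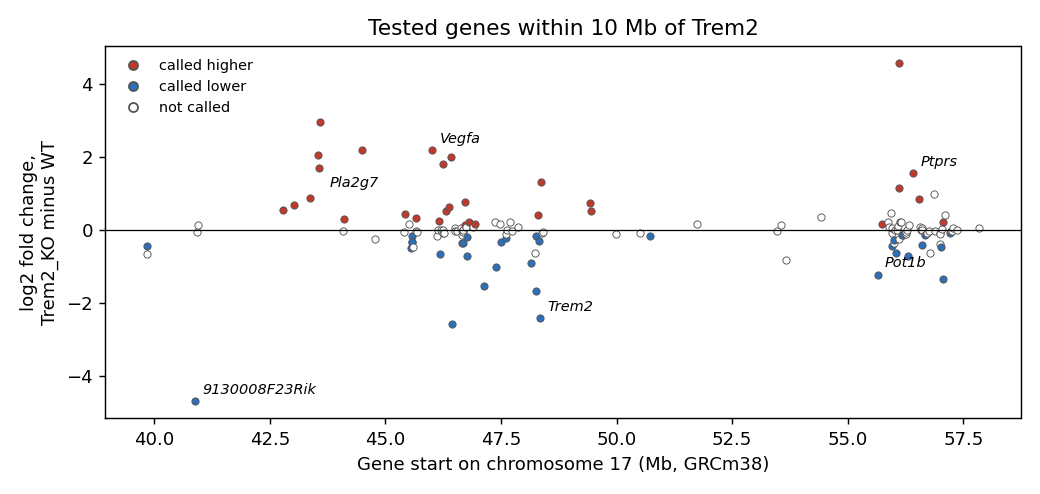
log2 fold change, Trem2_KO minus WT, of tested genes against gene start (Mb) on chromosome 17, within 10 Mb of Trem2, with filled points called. Guca1b, at 1.66 CPM in WT and with no read in Trem2_KO, was called lower and is not drawn. Its fitted log2 change of -7.76 rests on a group without reads. Called genes of both directions lie on either side of Trem2.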

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

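The fits with a fixed biological coefficient of variation were chosen after the data were seen. No called result changed direction under any alternative. Trem2 stayed called, with log2 changes from -2.47 to -2.12, and the odds ratio near Trem2 stayed above 1, from 1.74 without Trem2_KO replicate 1 to 6.03 at a fold of at least 2. Leaving out each library gave 3377 to 3909 called genes and 13 to 15 called lists. The count of 4181 moved to 358 (273 higher, 85 lower) at a fold of at least 2, to 1487 (938 and 549) with the coefficient fixed at 0.1, and to 371 (268 and 103) at 0.2, where more spread is assumed. Unfiltered log2(FPKM + 1) gave 2094 (1021 and 1073). Filtered FPKM gave 1340 higher and 1549 lower with a pseudocount of 1, and 1324 higher and 1534 lower with 0.1. DESeq2 gave 1428 higher and 1384 lower. The cause was not tested. Camera with an estimated correlation called 8 lists in place of 15 (3 higher, 5 lower), and fry, which does not compare a list with other genes, called 23 (12 higher). Lists with an estimated correlation under the preset 0.01 were among those lost (inflammatory cytokines, fatty acid synthesis and monocyte markers), so members that vary together do not explain every loss. With the replicate number as a block 4230 genes were called, and the immediate early list passed (adjusted p = 0.0464) while the erythroid list did not (0.0544). Same-numbered libraries did not deviate together (r across genes -0.00787 to 0.0361), so the numbers were not taken to pair samples. Of 2762 values of 146 named genes under alternatives, 79 lost and 10 gained a call. Of 657 list values, 26 lost and 21 gained one. A further 13 gene values and 13 list values changed sign without being called under either setting. Depth limits genes near 0.19 CPM, where 3 reads are expected.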

Other observations

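All tests in this part were chosen after the result was seen, except the other splits, the window around Trem2 and the gene length trend. The comparison with windows elsewhere and the lists of glucocorticoid, chaperone, clock, PPAR alpha and sex-biased genes were also chosen after the data were seen, so the counts of these lists describe these libraries and are not independent evidence. Of 22 tested glucocorticoid-responsive genes, 17 were called higher and 1 lower, with a median log2 change of 0.50. Ddit4 went from 42.4 to 259 CPM, Fkbp5 from 199 to 453 CPM and Klf9 from 38.3 to 96.2 CPM. Of 20 chaperone genes, 19 were called lower and 0 higher, with a median of -0.61, among them Hsph1 from 311 to 142 CPM and Bag3 from 92 to 42.7 CPM. Circadian clock genes, counted likewise, held 4 higher and 4 lower of 18. Higher were Per1 (0.89, also in the glucocorticoid list), Arntl (0.32), Bhlhe40 (0.20) and Clock (0.18). Lower were Dbp (-0.45), Nr1d1 (-0.28), Tef (-0.27) and Nr1d2 (-0.14). Clock genes need not move one way, so this even count does not show an unchanged clock. PPAR alpha targets held 12 higher and 1 lower of 20, with a median of 0.46.

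For the count of called genes, the real grouping called 4181 genes and the highest of the other splits called 0, so 1 of the 10 splits of the 6 libraries gave as many. With 10 splits a share under 0.05 cannot be reached.

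Calls near Trem2 were denser than elsewhere, with an odds ratio of 1.93, as DNA of another strain carried along with the knockout would give. Among 106 other windows of 20 Mb, 0 had as high an odds ratio, the highest being 1.67. For folds of at least 2 the highest elsewhere was 5.29 against 6.03. Flanking DNA of another strain is a candidate explanation for part of the calls in this window. It holds 9130008F23Rik, Plin4, Plin5, Vegfa and Hsp90ab1, which is in the chaperone list. Within 20 Mb the odds ratio was 1.80, so the same explanation stays open for the MHC class II genes on chromosome 17, though 4 of the 5 tested genes of that list elsewhere were also called lower. It stays open likewise for Hspa1a, Hspa1b, Flot1, Abcg1 and Tnf, which were called and lie within 20 Mb. Regulation that depends on Trem2 stays open for each single gene, since the strain history is not given in the sources used here.

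Of 27 lipid-associated macrophage genes, 14 were called higher. A lower share of Kupffer cells, with all other cells raised alike, would raise the markers of each. The hepatocyte and B cell lists held 14 called falls, 11 of them in the hepatocyte list, against 4 called rises in that list. Hepatocyte transcripts did not move together, so these 11 falls do not measure the share of hepatocytes. The other 3 are B cell markers, of which Cd79b lost its call without some single libraries. The count therefore cannot exclude a lower share with all other cells raised alike. A lower share beside more endothelial cells also stays open. Of 17 endothelial markers 14 were called higher and 1 lower, and of 24 resident Kupffer cell genes 19 were called lower and 2 higher. More recruited monocytes stay open. A set of 8 monocyte transcripts had a median log2 change of 0.105 (bootstrap interval -0.219 to 0.354), but 4 of them were under 1 CPM in both groups and the set left out the 5 members of the monocyte list that were called higher, among them Ccr2 (1.45). A change in endothelial cells stays open as well. With the gene length trend removed, 14 of the 14 called risers stayed called. A response to the loss of Trem2 is a hypothesis beside these.

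Hepatocyte transcripts did not move together: Cochran Q over its degrees of freedom was 59.8 for the list and Alb was at -0.05. This argues against a mere difference in the amount of hepatocyte RNA. The errors behind Q rest on a spread that may be technical, and the list holds Mup and Serpina1 genes whose values are uncertain. Falls were not confined to the Mup, Serpina1 and Cyp families. Slco1a1, Egfr, C8b and Nudt7 with Selenbp2 make 5 genes called lower by at least 1, though Selenbp2 has a close copy. These 5 genes were picked after their values were seen, so their count could not fail. The reads themselves were not examined, so reads shared between copies are not excluded. Of 10 male-biased genes outside the Mup, Serpina, Cyp, Ugt, Ces, Selenbp and Gst families, 6 were called lower, 5 of them by at least 1. A different state of the hepatocytes stays open. Male-biased liver genes had a median lower than female-biased ones by a difference of -2.02 (permutation p = 0.0377). That test decides nothing, since only 4 of 21 female-biased genes could be tested and the male-biased list was written after the largest falls had been seen.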
